A study of Trematomus bernacchii with 24 samples.

How the data were processed

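Small RNA was sequenced from the gill of the emerald rockcod, Trematomus bernacchii, a notothenioid fish of Antarctic coastal waters. The 24 libraries fall into 6 groups of 4 fish, kept at -1.5 °C (control) or +4 °C (warm) and sampled at day 7, 28 or 56. Per the labels' protocols, 5 fish were taken per time point and RNA of 4 per group was used, so each library stands for a separate fish. The tanks the fish shared are not given in the sources used here, so p-values measure the spread between fish and cannot separate temperature from tank. Per the labels, only RNA with an integrity number above 8 was used, libraries were made with the Illumina TruSeq small RNA kit and size-selected on a BluePippin, and 50 nt single-end reads were taken on 2 lanes of an Illumina instrument.

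The authors deposited 48 files, 1 per library and lane. Per the file headers, each lists distinct small RNA sequences with their length, their count, an expression value and a normalized value. The deposited count is a raw number of reads per distinct sequence and lane. The expression value equals it for every sequence, and the normalized value is that count scaled to the file's total (CPM); neither of these was used. The smallest deposited count is 3, so a sequence read fewer than 3 times in a lane is missing and a count of 0 means only that. The lanes hold 9557750 to 21470986 counted reads. Sequences are 15 to 46 nt long. The trimming program, aligner, miRNA database and their versions are not given in the sources used here.

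The deposited sequences differed from what the length rule chosen beforehand assumed. Most still carried a 3′ adapter starting AGATCGGAAGAGCACACGTC, and known miRNAs lacked their first 2 bases. The adapter was therefore removed by its first 10 bases, exactly, with 1 mismatch, or when the read ended after at least 6 of its bases. An exact adapter start was found in 89.8% to 97.6% of a library's counted reads. This adapter is not the known one of the kit that the labels name, and the sources used here do not explain the difference. The planned window of 18 to 25 nt was applied as 16 to 23 deposited bases. A sequence counted for a listed miRNA when positions 3 to 19 of the mature sequence occurred in it without mismatch. Its start had to lie within 2 bases of the 5′ end seen for known miRNAs. A sequence that began 1 or 2 bases beyond position 3 was matched from its own first base only. Members that differ only in the bases skipped could not be told apart in such sequences. Seed position 2 was thus not read, and members that differ only in positions 1, 2 or beyond 19 could not be told apart and carry a joint name (miR-200a-3p/miR-141-3p, miR-200b/c-3p). Counts of close members of the let-7, miR-10, miR-23, miR-29, miR-30 and miR-181 families stay uncertain where 1 base separates them.

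The list of 163 conserved vertebrate and fish miRNAs, with their 21 groups, was written from textbook knowledge. Names rest on sequence identity to that list; no genome position or hairpin was checked, so no coordinates are given. Of the listed names, 143 had counts. Then 11 were left out because their total was under 1% of a name 1 mismatch away, 14 had too few counts for edgeR's filterByExpr, and 118 were tested. Both lanes of a library were summed. Over 80 miRNAs with at least 100 CPM, lanes of a library correlated across miRNAs with r of at least 0.998. Counts of the 36 pairs of fish within groups differed by a chi-square of at least 480.3 per degree of freedom, so none of these pairs was a repeat; pairs from different groups were not compared.

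Tests used edgeR 4.0.16 (TMM scaling, glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment) in R 4.3.3, with all 24 libraries in 1 fit of 6 groups and no covariate; a miRNA was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.462 and scaling factors ran from 0.780 to 1.25. The contrasts were +4 against -1.5 °C at each day and averaged over the days, the temperature effect differing between days (F-test with 2 degrees of freedom), and the days within each temperature. Levels of miRNAs are CPM of the library's miRNA counts after TMM scaling. Levels of single sequences are CPM of the counts of all sequences tested, after their own TMM scaling. The 2 kinds of level are therefore not comparable. Groups with at least 3 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 64 tests of 16 groups. The share of counted reads matching a listed miRNA was compared by a two-sided permutation test within days with 100000 resamples. Each distinct sequence with at least 10 CPM in at least 4 libraries (4392 sequences) was also tested alone. Levels of 18 miRNAs fixed by name were to be given in every temperature comparison, with up to 12 called in each direction and, below 10 calls, the smallest p-values up to 10. This rule, the list, the groups, the tests and the alternatives were chosen before the data were examined.

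On data simulated from these libraries' means and depths, with 118 miRNAs, the test at 1 day recovered 35% of 2-fold and 88% of 4-fold changes and called 0.612% of the unchanged miRNAs. Averaged over the days it recovered 79% and 97%, with 1.43% of the unchanged ones called. A change present at 1 day only was recovered by the test of differing effects in 4% (2-fold) and 39% (4-fold), and day differences within a temperature in 32% and 86%. For 4392 sequences the shares were 35% and 80.3%, and for groups 100% at 2-fold. In the simulation miRNAs varied independently and all members of a changed group moved alike. In the data the estimated correlation within a group was 0.51 for miR-181 and 0.90 for striated muscle. The 100% therefore does not describe groups of correlated members.

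Library depth was 19286733 to 42575861 counted reads, and 886633 to 30309393 of these matched a listed miRNA. A miRNA at 1 CPM is thus 1 to 30 reads, near the listing minimum. Alternatives were DESeq2 size factors, total counts, DESeq2 1.42.0 as the test, no filter or at least 100 CPM, sequences starting at base 1 only, matching to position 17, no length limit, each lane alone, only the groups compared, the miRNA share as covariate, the replicate letter as block, and each fish left out. For single sequences, the reads matching a listed miRNA were used in place of total counts. Removing exact adapters only, and leaving out 4 libraries with a miRNA share under 35%, were added after the data were seen. Sequences of ribosomal and transfer RNA 5′ ends were recognised from a short list of motifs, also written after the data were seen.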

Results

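Gill small RNAs were counted in 24 emerald rockcod, 4 fish at each of -1.5 °C (control) and +4 °C (warm) on days 7, 28 and 56. The libraries held 19286733 to 42575861 counted reads (median 26035266.5), of which 886633 to 30309393 matched a listed miRNA. miR-200a-3p/miR-141-3p, from a family typical of epithelia, made up 13.8% ± 3.86 (SD, n = 24) of the miRNA counts. miR-146a-5p, a product of immune signalling, made up 13.1% ± 5.30, and miR-21-5p, often raised in injured tissue, 10.4% ± 2.94. The skin miRNA miR-203a-3p followed with 7.75% ± 1.62, let-7e with 5.40% ± 1.84 and miR-22a-3p with 5.22% ± 0.81. With the smooth muscle miRNA miR-143-3p, miR-200b/c-3p, let-7a and miR-100-5p, the 10 most abundant miRNAs held 70.1% ± 7.49 of the counts.

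The miRNA share of the counted reads showed how far other RNA filled the libraries. It was 57.2% ± 20.1 (SD, n = 4) in control and 47.1% ± 19.7 in warm fish at day 7. The shares were 35.4% ± 28.8 and 67.2% ± 5.97 at day 28, and 62.4% ± 11.3 and 76.3% ± 3.38 at day 56. Over the days warm fish were higher by 11.9 points, which a two-sided permutation test within days did not separate from the spread between fish (p = 0.142). The lowest shares were those of control day 28 fish c (4.46%) and b (17.4%), warm day 7 fish d (21.8%) and control day 7 fish d (30.9%). Without these 4 libraries the difference was 3.62 points. Starts of ribosomal RNAs held 5.58% ± 3.72 of the reads of control and 5.68% ± 3.25 of warm fish at day 7, 2.28% ± 1.46 and 2.77% ± 1.88 at day 28, and 3.95% ± 1.95 and 1.97% ± 0.54 at day 56. The 5′ fragments of transfer RNAs, which are cleaved under stress in many animals, held 5.84% ± 6.28 and 9.88% ± 6.40, then 5.44% ± 4.35 and 2.83% ± 0.93, then 3.46% ± 3.56 and 1.62% ± 1.51. Counting error is far smaller than these spreads between fish.

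**Figure D1:**
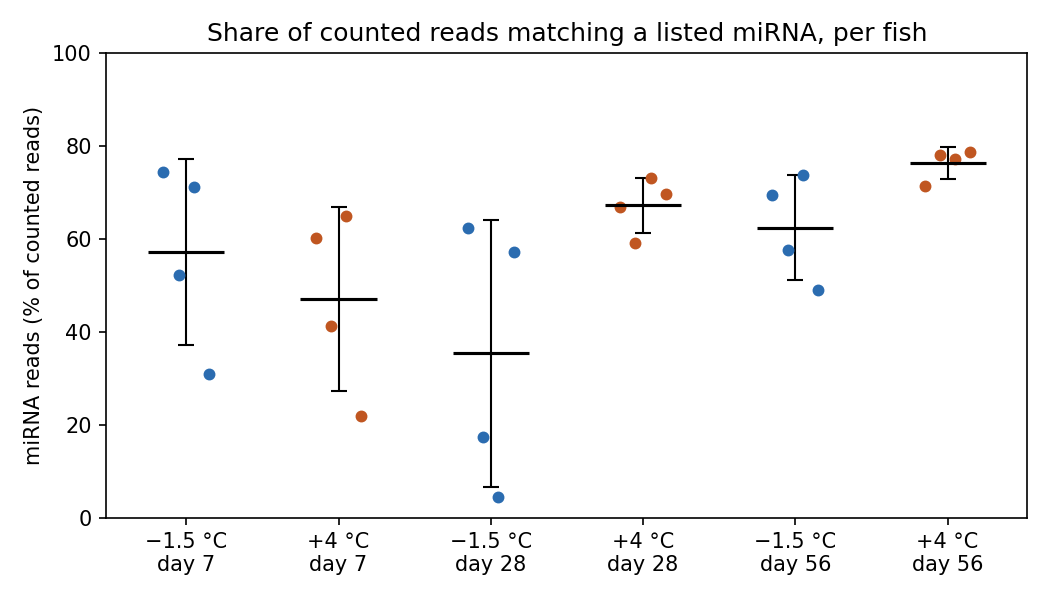
Share of counted reads matching a listed miRNA, in percent, for the 6 groups of 4 fish; points are fish, bars are means with SD. Control fish at day 28 range from 4.46% to 62.4%, while warm fish at day 56 average 76.3%.

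Fish held at +4 °C for 7 days were compared with those at -1.5 °C to find miRNAs that answered early warming. miR-155-5p, which activated macrophages and lymphocytes make, rose from 133 ± 38.0 CPM (counts scaled to library size; SD, n = 4) to 504 ± 100.3. miR-146a-5p, which restrains the signalling of innate immune receptors, rose from 68119 ± 15376 to 179228 ± 63609. The log2 difference was 1.92 ± 0.33 (SE) for miR-155-5p and 1.40 ± 0.29 for miR-146a-5p, and 4 of 4 warm fish lay above the control mean for each. Among other miRNAs of blood cells, the log2 difference was 1.08 ± 0.67 for miR-142-3p, 1.18 ± 0.62 for the red cell miRNA miR-144-3p and 0.05 ± 0.37 for miR-451a. The let-7 members let-7d and let-7a, which hold back proliferation, were at -0.60 ± 0.23 and -0.52 ± 0.24. Muscle's miR-1-3p was at -1.94 ± 1.03, miR-456-3p at 0.65 ± 0.28 and miR-489-3p at -0.81 ± 0.36, while miR-15a-5p and miR-190a-5p were near the listing minimum. The oxygen-sensitive miR-210-3p was at -0.21 ± 0.30, and the fish antiviral pair miR-462-5p and miR-731-5p at 0.35 ± 0.31 and 0.43 ± 0.42. For miR-34a-5p, a target of p53, the difference was 0.33 ± 0.50, for miR-21-5p 0.43 ± 0.28 and for the endothelial miR-126-3p -0.03 ± 0.51. The epithelial miR-203a-3p, miR-205-5p and miR-200b/c-3p were at -0.22 ± 0.23, 0.06 ± 0.43 and 0.18 ± 0.29. Values were -0.03 ± 0.30 for miR-143-3p, 0.15 ± 0.27 for miR-10b-5p, 0.15 ± 0.16 for miR-22a-3p and 0.49 ± 1.00 for the liver miRNA miR-122-5p. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 2 of 118 miRNAs were called, miR-155-5p with adjusted p = 8.12e-04 and miR-146a-5p with adjusted p = 0.00538; 7 had an unadjusted p under 0.05. Scaling by total counts moved the median of all miRNAs from 0.05 to -0.14.

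At day 28 miR-181a-3p, the arm of the miR-181a hairpin opposite to the one known to tune lymphocyte receptors, fell from 8390 ± 2903 CPM (SD, n = 4) to 1788 ± 671. miR-30c-5p, whose family holds back epithelial to mesenchymal change, fell from 9386 ± 2278 to 4005 ± 931. Their log2 differences were -2.23 ± 0.37 (SE) and -1.23 ± 0.33, with 4 of 4 warm fish below the control mean. miR-183-5p, made in sensory hair cells, was listed with 13, 0, 0 and 18 reads in the control fish and 0 in 4 of 4 warm fish, where a lane lists no sequence under 3 reads. miR-26a-5p, a brake on growth, was at -0.78 ± 0.22, let-7b at -0.89 ± 0.30, miR-456-3p at 0.90 ± 0.29, and miR-222-3p and miR-221-3p, usually made from 1 transcript, at -1.14 ± 0.38 and 0.66 ± 0.25. Near the listing minimum, miR-2187-5p had 35, 19, 33 and 22 reads in warm fish against 6, 3, 0 and 6, and miR-190a-5p 0, 10, 18 and 12 against 0 in 4 of 4 control fish. Neither was called. Control fish b and c had only 3356499 and 886633 miRNA reads, against 16278005 and 16210912 in a and d. Their low or absent counts of these miRNAs and of miR-183-5p thus say little. The 2 miRNAs called at day 7 stood at 0.43 ± 0.32 (miR-155-5p) and 0.35 ± 0.29 (miR-146a-5p). Muscle's miR-1-3p was at 2.30 ± 1.04, miR-126-3p at 1.00 ± 0.51, miR-34a-5p at 0.72 ± 0.53, miR-144-3p at 0.67 ± 0.61 and miR-122-5p at -0.88 ± 1.01. miR-210-3p stood at -0.51 ± 0.30, and miR-142-3p at 0.42 ± 0.66. The remaining fixed miRNAs ranged from -0.28 ± 0.43 (miR-205-5p) to 0.37 ± 0.16 (miR-22a-3p), with miR-462-5p at -0.14 ± 0.31 and miR-731-5p at -0.18 ± 0.42. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 3 miRNAs were called, all lower: miR-181a-3p (adjusted p = 5.18e-04), miR-30c-5p and miR-183-5p (adjusted p = 0.043 each). miR-26a-5p reached 0.0596, and 18 had an unadjusted p under 0.05. With no filter on low counts, both of the latter reached 0.0649. miR-30c-5p was not called either with sequences starting at base 1 only (0.111), lane 4 (0.0565) or lane 5 alone (0.0629), or with the miRNA share as covariate (0.0647). With matching to position 17, miR-183-5p was not called (0.103). miR-181a-3p was called with any 1 of the 8 fish left out. Leaving out control fish a, b or d or any of the warm fish ended the call of miR-30c-5p, and leaving out control fish a or d or any warm fish that of miR-183-5p (adjusted p = 0.076 to 0.176). The number of calls was 1 without control fish a or d or any warm fish, 2 without control fish b and 4 without control fish c.

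At day 56 the same 2 abundant miRNAs were low in the warm fish. miR-181a-3p fell from 9486 ± 3942 to 2088 ± 727 CPM (SD, n = 4; log2 -2.18 ± 0.37, SE), and miR-30c-5p from 9159 ± 2377 to 3668 ± 951 (-1.32 ± 0.33). let-7b fell from 5180 ± 1607 to 2398 ± 556 (-1.11 ± 0.30), and miR-199-5p, a miRNA of connective tissue, from 8046 ± 2442 to 3699 ± 923 (-1.12 ± 0.31). miR-221-3p, which favours proliferation, rose from 284 ± 73.9 to 608 ± 159 (1.10 ± 0.26), and miR-29b-3p, which represses collagens, from 49.8 ± 36.9 to 153 ± 74.8 (1.62 ± 0.46). miR-454-3p, of the miR-130 seed family, was listed with 0 reads in 4 of 4 control fish and with 18, 37, 41 and 28 in the warm fish. For each of the 7, 4 of 4 warm fish lay on the stated side of the control mean. miR-155-5p was at 0.73 ± 0.32 and miR-146a-5p at 0.67 ± 0.29. miR-26a-5p was at -0.67 ± 0.22, miR-181a-5p at -1.22 ± 0.45 and the red cell miRNA miR-451a at -0.92 ± 0.37; miR-2187-5p was near the listing minimum. The stress-related miR-34a-5p stood at 1.01 ± 0.49, miR-210-3p at -0.60 ± 0.30, miR-462-5p at -0.58 ± 0.31 and miR-731-5p at -0.73 ± 0.42. miR-126-3p was at 0.97 ± 0.51, miR-122-5p at -2.15 ± 1.04 and miR-1-3p at 0.80 ± 1.00, and the other fixed miRNAs lay between -0.43 (miR-144-3p) and 0.50 (miR-142-3p). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 7 miRNAs, with adjusted p = 6.81e-04 for miR-181a-3p, 0.00177 for miR-454-3p, 0.011 for miR-221-3p and 0.0167 for miR-30c-5p. The adjusted p was 0.0276 for let-7b and for miR-199-5p and 0.0322 for miR-29b-3p, and 27 had an unadjusted p under 0.05. With only the day 56 fish in the fit, miR-221-3p (0.0783), let-7b and miR-199-5p (0.0891 each) and miR-29b-3p (0.141) were not called. miR-29b-3p was not called in lane 4 (0.0794) or lane 5 alone (0.0585). Matching to position 17 pools it with miR-29a-3p, and the pool was not called (0.0613). let-7b was not called with at least 100 CPM (0.0559) or without the libraries of low miRNA share (0.0591), and miR-199-5p with at least 100 CPM (0.072) or sequences starting at base 1 only (0.0713). With 1 fish left out, miR-181a-3p and miR-454-3p were called in 8 of 8 cases. Calls ended without control d or warm a for miR-221-3p (adjusted p = 0.0505 to 0.0515) and without control b or d or warm a or b for miR-30c-5p (0.0578 to 0.171). They ended also without control b or d or warm a, b or d for let-7b (0.0525 to 0.203), and without control b or d or warm a, b or c for miR-199-5p (0.0911 to 0.179) and miR-29b-3p (0.0602 to 0.181). The number of calls was 2 without control d or warm a, and 3 without control b or warm b.

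Averaging the 3 days asked which miRNAs differed at +4 °C in the mean of the daily differences. A large difference at 1 day can carry such a call. Higher were the immune miRNAs miR-155-5p (log2 1.03 ± 0.19, SE, in 12 of 12 warm fish above their day's control mean) and miR-146a-5p (0.81 ± 0.17, 10 of 12), with 12 fish per temperature. miR-221-3p rose by 0.63 ± 0.15 (11 of 12), miR-456-3p, whose role is little known, by 0.70 ± 0.16 (12 of 12), miR-29b-3p by 0.97 ± 0.26 (12 of 12) and miR-24-3p, active in vessels and blood, by 0.34 ± 0.11 (11 of 12). miR-181a-3p was lower by the most of the abundant miRNAs (-1.68 ± 0.21, 0 of 12 above), with miR-30c-5p at -0.90 ± 0.19 (1 of 12), let-7b at -0.75 ± 0.17 (0 of 12) and miR-26a-5p at -0.59 ± 0.13 (1 of 12). miR-222-3p fell by 0.76 ± 0.22 (2 of 12) while its transcript partner miR-221-3p rose. Also lower were miR-23b-3p (-0.49 ± 0.14, 0 of 12), miR-199-5p (-0.59 ± 0.18, 2 of 12) and miR-30a-3p (-0.52 ± 0.17, 1 of 12). Near the listing minimum, miR-454-3p, miR-190a-5p and miR-2187-5p were higher and miR-183-5p lower, with at most 41, 39, 36 and 36 reads in a fish (adjusted p = 0.00119, 0.00843, 0.00839 and 0.00836 by edgeR). Single lanes ended 2 of these calls. In lane 4 alone miR-190a-5p had adjusted p = 1.00 by edgeR beside a fitted log2 difference of 3.98 (4.62 with both lanes), so with so few reads that p does not show the difference gone, and miR-2187-5p was at 0.158 in lane 5 alone. miR-21-5p was at 0.39 ± 0.16, miR-34a-5p at 0.69 ± 0.29, miR-126-3p at 0.65 ± 0.29, miR-210-3p at -0.44 ± 0.17, miR-22a-3p at 0.21 ± 0.09 and let-7a at -0.28 ± 0.14, none of them called. Nor were miR-462-5p (-0.12 ± 0.18), miR-731-5p (-0.16 ± 0.24), miR-451a (-0.24 ± 0.21), miR-144-3p (0.47 ± 0.35), miR-142-3p (0.67 ± 0.38) and miR-122-5p (-0.84 ± 0.58). The same held for miR-203a-3p (0.15 ± 0.13), miR-205-5p (-0.19 ± 0.25), miR-200b/c-3p (0.08 ± 0.17), miR-143-3p (-0.13 ± 0.17), miR-10b-5p (0.16 ± 0.16) and miR-1-3p (0.39 ± 0.57).

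edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 18 of 118 miRNAs over the days, 9 higher and 9 lower, and 34 had an unadjusted p under 0.05. The adjusted p was 6.32e-06 for miR-181a-3p, 8.16e-04 for miR-155-5p, 0.00198 for miR-146a-5p and miR-30c-5p, and 0.00268 for miR-26a-5p. miR-221-3p, let-7b and miR-456-3p had 0.00383, miR-29b-3p 0.0114, miR-23b-3p 0.0132, miR-222-3p 0.0151 and miR-199-5p 0.0207. The weakest calls were miR-30a-3p (0.031) and miR-24-3p (0.0316). With total counts as the scaling 23 miRNAs were called, 8 higher and 15 lower, as the median of all miRNAs moved from 0.07 to -0.08, and miR-24-3p was no longer called (0.263). It was not called either in lane 4 (0.122) or lane 5 alone (0.0691) or with matching to position 17 (0.0642). That matching also ended the call of miR-30a-3p (0.0532), then pooled with the rare miR-30e-3p. It pools miR-23b-3p with miR-23a-3p, and the pool was not called (0.149). In the main counts miR-23b-3p had 111013 reads and miR-23a-3p 551176, so the pool does not test miR-23b-3p alone. miR-30a-3p was not called without a filter (0.0554), with at least 100 CPM (0.0513) or with sequences starting at base 1 only (0.0674), nor was miR-199-5p in the last (0.0697). Leaving out 1 fish ended the call of miR-24-3p for control day 7 b or d, control day 28 d, control day 56 d, warm day 28 a or b and warm day 56 b or c (adjusted p = 0.0501 to 0.0704). The call of miR-30a-3p ended without control day 7 c, control day 28 d, control day 56 b or d, warm day 7 c or d, warm day 28 b or c, or warm day 56 b (0.0505 to 0.0958). That of miR-199-5p ended without control day 7 d or control day 56 b or d (0.0501 to 0.0541). Without the 4 libraries of low miRNA share, miR-29b-3p (0.0577), miR-23b-3p (0.0894), miR-222-3p (0.127) and miR-199-5p (0.135) were not called.

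**Figure D2:**
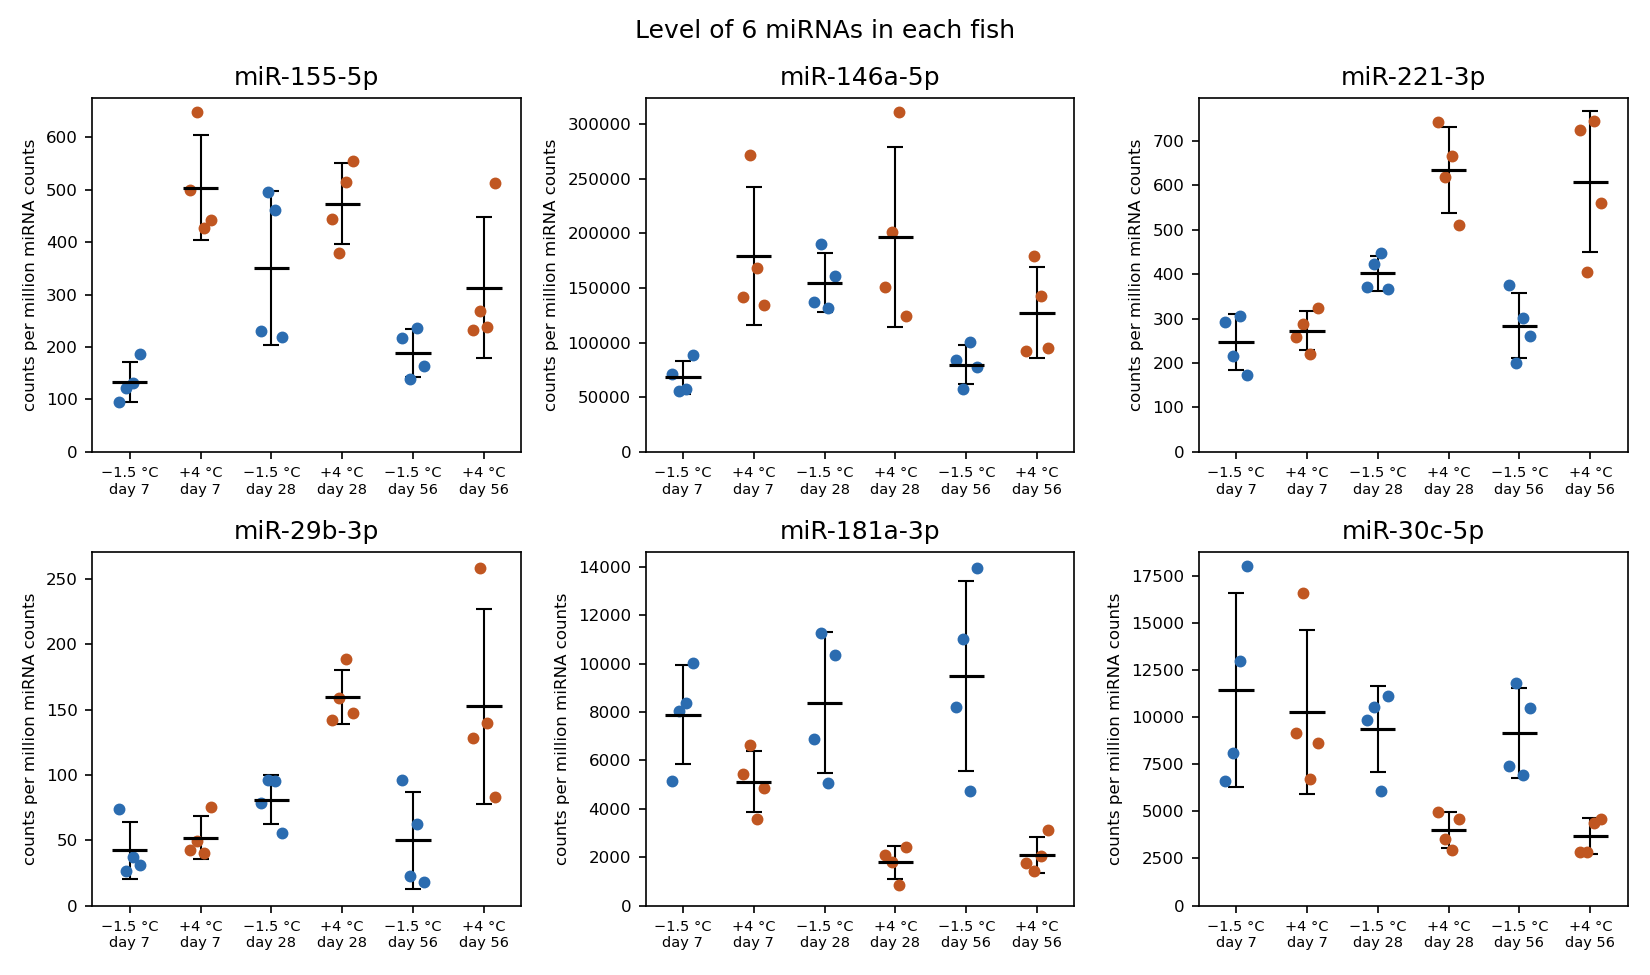
Level in CPM of 6 miRNAs in each fish at -1.5 and +4 °C on days 7, 28 and 56; points are fish and bars are means with SD (n = 4). miR-155-5p and miR-146a-5p part most at day 7, and miR-181a-3p lies low in the warm fish of days 28 and 56.

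Groups of related miRNAs were tested to see whether they moved as sets. The leukocyte group was higher at day 7, where 2 of 6 measured members, miR-155-5p and miR-146a-5p, rose and 4 were not called (miR-142-3p 1.08, miR-142-5p 0.28, miR-150-5p 0.32, miR-223-3p 0.84, all log2). Its median was 0.96, and camera gave adjusted p = 8.61e-04, and adjusted p = 0.0318 with an estimated correlation; 2 were called adjusted over the list alone. The miR-181 group, with 3 measured members that include miR-181a-3p and miR-181a-5p, was lower at day 28 (median -0.62), day 56 (-1.22) and over all days (-0.60). At each, 1 member fell, and 1, 2 and 3 were called adjusted over the list alone. Camera gave adjusted p = 0.0198, 0.0394 and 0.0221 for them, and adjusted p = 0.572 with an estimated correlation in each case. The let-7 group was lower at day 7 (median -0.31, 0 of 8 members called, 0 adjusted over the list alone) with camera adjusted p = 0.0198, and adjusted p = 0.572 with an estimated correlation. These were the 5 calls among 64 tests of 16 groups, against 1 with an estimated correlation and 7 by fry. None of the 5 was called without the 4 libraries with a low miRNA share (adjusted p = 0.102 to 0.187). The let-7 call ended also without control day 7 c or warm day 7 b or d (highest adjusted p 0.315). The miR-181 call at day 56 ended without control day 56 a, warm day 7 b or d or warm day 56 b (highest 0.112), under total counts (0.0548), with at least 100 CPM (0.0865) and with the miRNA share as covariate (0.0554).

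Over all days the other groups had no camera call. The median log2 difference was 0.59 for leukocytes (2 of 6 rose, 2 adjusted over the list alone), 0.94 for the group of miR-130, miR-301 and miR-454 (miR-454-3p rose, 3 measured, 1 adjusted over the list alone) and 0.37 for the miR-17-92 related group, known from proliferating cells (0 of 9 called). let-7 stood at -0.29, where let-7b fell and 2 of 8 were called adjusted over the list alone, and the miR-30 group at -0.20, where miR-30c-5p fell (1 of 4, 1 adjusted over the list alone). In the miR-23/27/24 group miR-24-3p rose and miR-23b-3p fell (median 0.01, 6 measured, 2 adjusted over the list alone). miR-199-5p fell in the smooth muscle and mesenchyme group (-0.14, 5 measured, 1 adjusted over the list alone) and miR-183-5p in the sensory cluster (-0.07, 3 measured, 1 adjusted over the list alone). The hypoxia and damage group, with miR-210-3p and miR-21-5p, had a median of -0.12 and a mean of 0.07; 0 of 5 were called, 3 adjusted over the list alone. With 0 called over all miRNAs or adjusted over the list alone, the medians were 0.15 for epithelial (5), 0.04 for cartilage (4), -0.08 for Hox-linked (8), -0.16 for neural (4), -0.04 for striated muscle (4) and -0.01 for liver and gut miRNAs (3 measured). Groups with under 3 measured members were not tested; their medians were -0.33 (endocrine), 0.52 (endothelial), 0.12 (erythroid), 0.14 (miR-15/16) and -0.03 (pancreas).

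Whether the temperature difference itself changed with the day was tested directly. miR-181a-3p went from -0.62 ± 0.36 (log2, SE, n = 4 per group) at day 7 to -2.23 and -2.18 later, and miR-155-5p from 1.92 ± 0.33 to 0.43 and 0.73. miR-30c-5p, miR-221-3p, miR-1-3p, miR-375-3p and miR-146a-5p also had an unadjusted p between 0.0257 and 0.0492, as had miR-15a-5p, miR-454-3p and miR-183-5p near the listing minimum. In edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment 0 of 118 miRNAs were called and 10 had an unadjusted p under 0.05; DESeq2 called 0. The smallest p was 0.00575 for miR-181a-3p and 0.00812 for miR-155-5p (adjusted p = 0.479 each), so no change of the temperature effect between days passed the adjustment. On simulated data this test found 39% of 4-fold changes confined to 1 day.

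**Figure D3:**
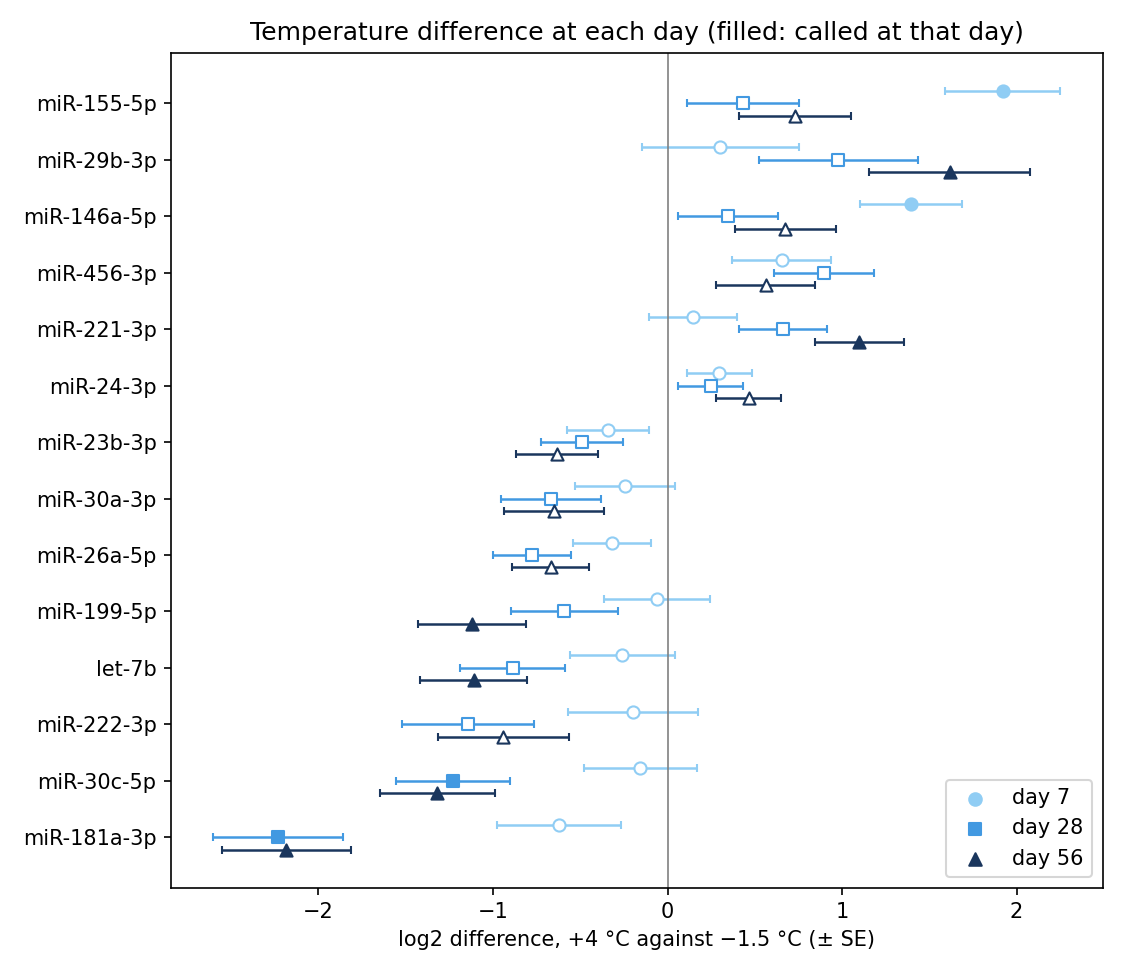
Log2 difference between +4 and -1.5 °C with SE for 14 miRNAs at days 7, 28 and 56 (n = 4 fish per group and day); filled points were called that day. miR-155-5p and miR-146a-5p are called at day 7, and miR-181a-3p and miR-30c-5p at days 28 and 56.

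Time in the aquarium was examined within each temperature. In control fish miR-155-5p and miR-146a-5p differed between days, being higher by 1.40 ± 0.33 and 1.18 ± 0.29 (log2, SE) at day 28 than at day 7, and by 0.50 ± 0.32 and 0.23 ± 0.29 at day 56. The liver miRNA miR-122-5p was at -3.39 ± 1.10 and -2.40 ± 1.05 against day 7 and was not called. edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment gave 0.0457 for both immune miRNAs, the 2 calls at -1.5 °C, and 10 had an unadjusted p under 0.05. These calls were fragile: 0 miRNAs were called without control day 7 a, b or c, control day 28 b or c, or control day 56 b or d, 1 without control day 28 a or d and 3 without control day 56 a. For these losses the adjusted p was 0.076 to 0.346, and it was 0.825 (miR-155-5p) and 0.697 (miR-146a-5p) without the libraries of low miRNA share.

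In warm fish 18 miRNAs differed between days (43 at an unadjusted p under 0.05) by the same edgeR test. miR-122-5p went from 1355 ± 1044 CPM (SD, n = 4) at day 7 to 49.9 ± 24.5 and 41.2 ± 15.3 (log2 -4.76 ± 1.17 and -5.04 ± 1.19, SE, at days 28 and 56). Muscle's miR-1-3p went from 196 ± 127 to 4165 ± 4492 and 3276 ± 1889 (4.41 ± 1.14 and 4.07 ± 1.12). miR-30c-5p (-1.36 ± 0.33 and -1.48 ± 0.33), miR-181a-3p (-1.52 ± 0.36 and -1.30 ± 0.36) and miR-199-5p (-1.40 ± 0.31 at day 56) were lower on both later days. miR-221-3p (1.22 ± 0.26 and 1.16 ± 0.26) and miR-29b-3p (1.62 ± 0.46 and 1.55 ± 0.46) were higher on both. The antiviral pair was lower on both, miR-731-5p at -0.96 ± 0.42 and -1.76 ± 0.43 and miR-462-5p at -0.54 ± 0.31 and -1.19 ± 0.32. Lower on both days were miR-222-3p, miR-26a-5p, miR-375-3p, let-7b, miR-128-3p, miR-100-5p and miR-217-5p, from -0.58 (miR-26a-5p, day 56) to -1.77 (miR-217-5p, day 28), and miR-31-5p, a miRNA of wounded epithelia, was at 0.61 and -2.64 ± 0.80. miR-15a-5p, the eighteenth, had 3 or 4 reads per fish at day 7 and 14 to 27 later. Benjamini-Hochberg adjusted p was 0.00628 for miR-122-5p, miR-30c-5p and miR-221-3p, 0.00894 for miR-199-5p and miR-181a-3p, and 0.0214 to 0.0354 for the rest.

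Those 5 warm-fish calls held with any 1 of the 12 fish left out, and 13 did not. Without warm day 7 a only 6 miRNAs were called, without warm day 56 b 9, without warm day 7 b 11 and without warm day 7 d 46. Without warm day 7 a, 12 of these 13 ended, and miR-31-5p, the exception, ended without warm day 56 a or d (adjusted p = 0.0644 to 0.082). Warm day 7 b was also needed for miR-222-3p, miR-731-5p, miR-1-3p, let-7b, miR-29b-3p, miR-462-5p, miR-128-3p and miR-15a-5p, and warm day 7 c for miR-26a-5p, miR-29b-3p, miR-128-3p, miR-100-5p, miR-217-5p and miR-15a-5p. Among day 56 fish, b was needed for miR-731-5p, miR-375-3p, let-7b, miR-29b-3p, miR-462-5p, miR-128-3p, miR-100-5p, miR-217-5p and miR-15a-5p, and a, c or d for some of miR-462-5p, miR-375-3p, miR-128-3p, miR-100-5p and miR-217-5p. Single day 28 fish were needed for miR-100-5p (b, c, d), miR-217-5p (a, c, d) and miR-15a-5p (c). Over these losses the adjusted p was 0.0513 to 0.213. With only the warm fish in the fit, miR-26a-5p (0.0843), miR-31-5p (0.0532), let-7b and miR-462-5p (0.0612 each), miR-128-3p (0.0727), miR-100-5p (0.0567) and miR-217-5p (0.083) were not called. Lane 4 and lane 5 alone ended the call of miR-217-5p (0.0574 and 0.0596), and lane 5 that of miR-15a-5p (0.421). The miRNA share as covariate ended miR-15a-5p (0.0972) and let-7b (0.055), and leaving out the libraries of low share miR-375-3p (0.0605).

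Testing single sequences covered small RNAs outside the list used here. Being outside this list does not make a sequence unknown. None was searched in a database, so these may include other arms of listed hairpins. The sequence with the smallest p, CATCGACCGTTGACTGTGCC, was lower at +4 °C, at 91.1 ± 59.3 against 844 ± 470 CPM (SD, n = 12; log2 -3.17 ± 0.28, SE). It differs by 2 mismatches from CATCGACCGTTGATTGTACC, the most counted form of miR-181a-3p, and the related CCATCGACCGTTGACTGTGCC was at -2.91 ± 0.33. Also lower were CTCAGTAGTCAGTGTAGATCCT (-2.44 ± 0.26), GGGTTGGGCTCTTGGGAGCT (-1.92 ± 0.23) and GAGCTTAGCTGATTGGTGAAC (-1.81 ± 0.18). Higher were ACAACAGTCTGTAGGCTGA (2.68 ± 0.35, 200.4 ± 226.8 against 19.3 ± 12.9 CPM) and its shorter form ACAACAGTCTGTAGGCTG (2.36 ± 0.34). TAATTCTGAGCTCCAGC was at 2.15 ± 0.33, CTGGAAACTTTGCCTGGG at 1.85 ± 0.22 and TATGGGCTTAGTTCTTTTGA at 1.66 ± 0.26. The adjusted p of these 10, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, ran from 8.72e-07 to 2.26e-04.

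Of 4392 sequences, 704 were called over the days, 393 higher and 311 lower. Among 1395 forms of listed miRNAs 308 were called (177 higher, 131 lower), and among 2997 others 396 (216 higher, 180 lower). By day the counts were 48 (34 higher, 14 lower) at day 7, 287 (101 and 186) at day 28 and 391 (247 and 144) at day 56. The risen sequences averaged 19.2 nt, the fallen ones 20.3 nt and the others 19.6 nt. Days differed for 23 sequences at -1.5 °C and for 1892 at +4 °C, but a temperature effect differing between days was called for 0 sequences. These counts alone therefore do not show that time mattered more at +4 °C. Scaled instead by each library's reads matching a listed miRNA, without TMM, the median of all sequences moved from -0.09 to -0.50. Then 1036 were called, 191 higher and 845 lower. These reads held a larger mean share in warm fish at days 28 and 56, so this divisor by itself lowers other sequences there. Scaling by all counts of the sequences was not run. The balance of directions thus depends on the scaling chosen. With TMM scaling and without warm day 7 d, 1116 were called.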

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

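Tests of the low day 7 controls, of leukocytes and of reads moved to shorter forms were chosen after the result was seen; the other tests here were written before. The levels of 23 miRNAs called in some comparison with a mean of at least 10 CPM, the miRNA share and the depth, 25 measures in all, were examined in each of the 6 groups for a fish far from the other 3. This held in 2 of 150 cases, fewer than the 1 in 20 that chance gives. miR-100-5p was high in warm day 56 fish a (14.50 against 14.28 to 14.29, log2 CPM), the gap being 0.946 of the group's range. miR-122-5p was low in control day 28 fish b (5.14 against 6.76 to 6.81), the gap being 0.972 of the range. That fish's library had a low miRNA share (17.4%), and no explanation of either was tested.

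Warm fish had more miR-155-5p and miR-146a-5p at day 7 (log2 1.92 ± 0.33 and 1.40 ± 0.29, SE). The tables argue against the unequal miRNA share of the libraries as the whole reason, since with the share as covariate the differences kept 97.3% and 100.3% of their size. Unusually low day 7 controls stay open: the warm fish lay above the mean of the later control groups by 0.97 ± 0.27 (miR-155-5p) and 0.69 ± 0.24 (miR-146a-5p), but above day 56 controls by 1.42 ± 0.32 and 1.17 ± 0.29 and above day 28 controls by only 0.52 ± 0.32 and 0.21 ± 0.29, under 2 SE (the mean alone had first been read as excluding it). More leukocytes in the warm gills stays open too: the other 4 leukocyte miRNAs had a median of 0.58 (SD 0.39), and their errors of 0.37 to 0.67 are too wide to tell this from the 1.40 of miR-146a-5p. A first reading by the SD alone had counted against leukocytes, and the members' own errors were added to the bound afterwards; an immune response to warming or a difference between tanks was not tested and may also underlie it.

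Warm fish had less miR-181a-3p at days 28 and 56 (log2 -2.23 ± 0.37 and -2.18 ± 0.37). With the miRNA share as covariate the differences kept 100.2% and 100.1%, which argues against the share as the reason. Other abundant miRNAs were slightly shorter in warm fish, with a median of -0.116 nt at day 28 (71 of 79 shorter) and -0.134 nt at day 56 (70 of 79; permutation p = 0.0144 over all days), and the full-length part of miR-181a-3p went from 82.0% to 43.0% and from 87.5% to 62.1%. This met what a general shortening was said beforehand to give. A move of reads to shorter forms that keep the first 14 deposited bases of miR-181a-3p cannot be the whole reason. All reads with these bases, of any length, differed by -2.29 ± 0.43 and -2.15 ± 0.42 (log2, SE). The full-length form differed by -3.23 ± 0.57 and -2.64 ± 0.48, the other counted forms by -0.59 ± 0.32 and -0.58 ± 0.30. Reads cut into these bases at either end would leave the total, so shortening that far stays open. This total replaced a first test on the shorter forms alone, which did not ask whether the total fell. A biological effect of temperature remains a hypothesis, and tanks were not given.

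Within warm fish miR-1-3p was higher and miR-122-5p lower on the later days (mean log2 4.24 and -4.90 against day 7). Liver or gut RNA in the day 7 samples may bring miR-192-5p and miR-194-5p along. Their median was -0.157 (SD 0.74, with 0.37 and -0.68), at levels of 54.3 ± 21.6 and 8.32 ± 1.39 CPM at day 7. By the bound written beforehand this counted against liver or gut RNA as the source of miR-122-5p. The proportion of these miRNAs in such RNA was not measured, however, so that source stays open. miR-122-5p was also lower on the later days in control fish, where it was not called. Muscle carried over with the gill may explain miR-1-3p: miR-206-3p, miR-133-3p and miR-499-5p were also higher, with a median of 2.12 (SD 0.43), though less than miR-1-3p; on the later days they reached 994 ± 436, 37.4 ± 24.2 and 179 ± 59.7 CPM against 3721 ± 3225 for miR-1-3p. The bound written beforehand would exclude muscle on that SD, but it was wrong to leave out the errors of the changes themselves, 0.84 to 1.14, so muscle stays open. An effect of days at +4 °C was not tested apart from these.

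Other splits of the same fish were used to see whether chance gives as many calls. Of the 35 splits of a day's 8 fish, only the real one gave as many calls on each day. The real and highest other counts were 2 and 1 at day 7, 3 and 0 at day 28, and 7 and 2 at day 56. Such counts were thus rare among the splits, though 1 of 35 is the smallest share this test can give. Of 100 splits that exchanged temperatures within days, the real one included, 2 gave as many as the 18 calls over all days. For the 5 group calls it was 4 (highest other 5), and for the 704 sequences 1, the real one (highest other 610). Such counts were thus uncommon, but for miRNAs and groups not beyond what other splits gave. The highest other split over all days gave 39 calls, more than the real one; what sets that split apart was not tested. For differing effects the real count was 0 (highest other 3), which all 100 splits reach by construction, so the splits say nothing there. Of 100 splits of days within temperatures, 2 gave as many as the 2 calls at -1.5 °C (highest other 3). As many as the 18 at +4 °C came from 3 (highest other 25). Other splits thus passed both real counts, though rarely. Exchanging fish cannot separate temperature from tank.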

How the results depend on the processing

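Removing exact adapters only and leaving out the 4 libraries with a low miRNA share were chosen after seeing the data; the other settings were planned. Named results, counted once per setting or fish left out, include many not called in the main fit. Those count as staying while they remain uncalled. Only called results can be lost, so the numbers that stayed do not measure how stable the calls are. Under other settings 2364 stayed on their side of the threshold, 82 were no longer called, 16 became called and 0 changed sign while called. With 1 fish left out 2365 stayed, 6 became called, 0 changed sign while called and the rest were no longer called. miR-155-5p at day 7 and miR-181a-3p at days 28 and 56 stayed called under each setting and each fish left out. DESeq2 as the test called 6 at day 28, 34 between days at +4 °C and 1098 sequences. Testing without a filter, sequences starting at base 1 only, lane 4 or lane 5 alone each left 1 call at day 28 and 0 between days at -1.5 °C, where DESeq2 size factors, total counts, the miRNA share as covariate and leaving out the low-share libraries also gave 0. A mean of at least 100 CPM, which tests fewer features, called 4 at day 56, 11 over all days and 175 sequences, and a floor of 50 CPM 348 sequences. Using only the samples of the groups compared, thus fewer fish for the spread, called 3 at day 56 and 1 at -1.5 °C. The replicate block called 1 at day 7, 1 at day 28, 3 at day 56, 11 over all days and 1 at -1.5 °C, 19 at +4 °C, 5 groups and 534 sequences, but letters did not pair fish: over 12 pairs correlations ran from -0.53 to 0.36, and 3 fish were closest to their own letter. Leaving out the low-share libraries called 45 between days at +4 °C and 0 groups, and camera with an estimated correlation 1 group. Leaving out 1 fish gave 2 to 2 calls at day 7, 1 to 4 at day 28, 2 to 7 at day 56, 15 to 21 over all days, 0 to 0 for differing effects, 0 to 3 at -1.5 °C, 6 to 46 at +4 °C, 3 to 5 groups, 504 to 1116 sequences and a share difference of 8.44 to 14.9 points. Where no construction is named, the cause was not tested. Sequences were not run without a filter, and for all days, differing effects and sequences the groups compared are all 24 fish. Depth limits miRNAs near 3 reads per lane, whose calls rest on few reads.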

Other observations

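The deposited sequences still carried an adapter that starts AGATCGGAAGAGCACACGTC and known miRNAs lacked their first 2 bases. Reads longer than the length window held 16.2% ± 20.4 (SD, n = 4) in control and 20.8% ± 11.4 in warm fish at day 7, 21.0% ± 16.4 and 6.43% ± 2.84 at day 28, and 7.26% ± 7.14 and 2.81% ± 2.34 at day 56. In day 7 fish, the full-length part of miR-181a-3p was 87.7% ± 2.05 in controls and 72.4% ± 9.98 in warm fish, and other abundant miRNAs differed by a median of -0.00765 nt in length.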
